A study of Homo sapiens with 12 samples.

How the data were processed

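The data are 12 Affymetrix exon arrays of human epidermis, 3 each from palm, sole, back of hand and back of foot, with the epidermis parted from the dermis by dispase and the RNA labelled from random primers. The deposited table gives one value per probe set and array, normalized between arrays by the authors, and the values are on a log2 scale as read from their range of 1.35 to 14.3. Per the submitters' processing notes, Affymetrix Expression Console and PLIER were used with build hg19. Their versions, the log base, the offset and the normalization target are not given in the sources used here. The medians of the arrays lie within 0.123 of one another. Array values have no depth in counts and no detection calls were used, so the background is unknown and dim genes are measured with unknown precision. The number of arrays limits the precision: the median standard error was 0.120 for volar against non-volar and 0.170 for a pair of sites.

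Of 44726 table entries, 21292 name 1 gene, 4327 name several and 19107 name none. Only entries naming 1 gene were compared gene by gene, and the entry with the highest mean over the 12 arrays stood for each of the 2474 genes with several entries, which gave 17393 genes. Entries naming several genes or none were tested separately between volar and non-volar arrays with limma, where 0 passed. Gene names were matched to a GRCh38.p14 RefSeq table for names only, and no positions are given since the arrays' own build differs. Entries of Y-linked genes and XIST, 32 in all, were left out. KRT6A, KRT16, KRT5, FLG, HOXA13 and TYR have no entry of their own and were not analysed here. Among 13 called genes with several entries 1, IRAK3, has an entry of the opposite sign. No pair of arrays had repeated values: at least 99.99% of entries differed.

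Genes were compared with limma 3.58.1 in R 4.3.3 in a single model with a mean per site, whose spread estimate has 8 residual degrees of freedom and 3.53 from the prior. Benjamini-Hochberg adjusted p-values under 0.05 over all genes count as passed. The contrasts were volar against non-volar, palm against back of hand, sole against back of foot, the difference of these pairs, lower against upper extremity, sole against palm, and back of foot against back of hand. The volar contrast is the mean of the hand and the foot pair. Of 40 gene lists, 38 with at least 3 measured genes were tested per contrast with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a contrast. A fry p-value tests whether a list's genes move one way on balance and does not compare them with other genes. Palmoplantar and stress keratins had 1 measured member, KRT9, and HOXA genes had 1, HOXA2, so these lists were not tested. The comparisons, gene lists, naming rule and alternatives were fixed before the data were examined, except those said to be added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

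Genes are named by a rule. For volar against non-volar and for the extremities it takes the 10 largest rises and 10 largest falls among passed genes with all 3 arrays of one site beyond all 3 of the other in both site pairs. For each other contrast it takes the 5 largest rises and falls among passed genes. For each list it takes up to 4 passed members, or up to the largest few when none passed, and a fixed set of keratinocyte, limb and cell type genes is always named. Genes outside the rule are said to be named after their values were seen, and members printed as examples adjusted over a list alone were chosen in the same way.

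The p-values measure the spread between samples. The labels speak of distinct donors and do not state whether a replicate number marks the same donor at several sites. Residuals after the site means correlated above 0.1 in 17 of 18 pairs of arrays with the same replicate number, with a median of 0.286 against -0.149 for other pairs, and each of 12 arrays correlated best with an array of its own number. The residuals of a site cancel out, so the negative value for other pairs largely follows from the positive one and is not separate evidence. The lowest value was 0.308 for palm and back of hand, 0.205 for palm and sole and 0.223 for the backs of foot and hand. For sole and back of foot it was 0.0279, so the condition for a paired model was met by the first 3 of these pairs only. The 0.0279 came from replicate 1, whose back of foot array correlated least with the other arrays. Replicates 2 and 3 gave 0.126 and 0.394. The lowest value was 0.269 for back of foot and palm and 0.213 for back of hand and sole. If the numbers mark donors, the unpaired model ignores a pairing in the volar and sole comparisons too. Values with the replicate number as a block are given beside the results of the pairs that met this condition.

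Alternatives were a pseudocount of 16 on the linear scale, quantile normalization, median centring, leaving out the dimmest 33% of genes, an intensity trend with robust variance, array weights, the replicate number as a fixed and as a random block, fitting only the sites compared, the mean of all entries of a gene, leaving out each array, a minimum log2 change of 1, and an adjusted p of 0.1. Added after the data were seen were leaving out the pair of arrays with the lowest mean correlation, and testing all table entries together. In a test on simulated data with 200 changed genes in each of 10 runs, the volar contrast recovered 87.7% of changes of 1 and 99.0% of changes of 2 on the log2 scale, with 9.7 false calls on average. A pair of sites recovered 67.9% (hand) and 67.3% (foot) of changes of 1. A list lowered by 0.5 was found in 10 of 10 runs. The simulated genes varied independently of one another and without an effect of the replicate number, which differs from the real arrays. These runs therefore do not test the list calls where genes of a list vary together.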

Results

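Gene expression was measured in epidermis from 12 skin samples on 12 arrays. The palm and the sole are volar skin, the ridged and hairless surface of hands and feet, and the backs of the hand and foot are non-volar skin of the same extremities. Each of the 4 sites had 3 arrays, so volar and non-volar epidermis had 6 arrays each. The median log2 value per array lay between 5.16 and 5.28. Values ran from 1.35 to 14.3 over all arrays. The number of arrays limits the precision. After one row was taken per gene, 17393 genes were compared. Back of foot replicate 1 had the lowest mean Spearman correlation with the other arrays, across table entries, at 0.932. Palm replicate 1 followed at 0.948, and the highest was 0.965. Changes below are on the log2 scale, the value after ± is the standard error of limma's estimate unless named SD, and adjusted p is over all genes unless said otherwise.

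The first comparison asked which genes differ between volar and non-volar epidermis when hand and foot weigh equally. KRT9, the keratin typical of palm and sole epidermis, showed the largest rise: 4.94 ± 0.63 (n = 6 against 6 arrays, adjusted p = 0.00722 in limma), or 30.6-fold. Its mean was 11.7 ± 1.65 (SD, n = 6) in volar and 6.80 ± 0.524 (SD, n = 6) in non-volar arrays. ITGBL1, which encodes a secreted integrin beta-like protein, rose by 2.52 ± 0.25 (adjusted p = 0.00165). The water channel gene AQP5 rose by 1.76 ± 0.22 (adjusted p = 0.00722), or 3.38-fold. PPM1K, which encodes a mitochondrial phosphatase of branched-chain amino acid breakdown, rose by 1.44 ± 0.08 with the smallest adjusted p, 2.86e-05. It is dim, at 4.19 to 4.47 in non-volar arrays, below the array medians. Its change was as low as 0.96 over the 20 alternatives that include it, and it passed in all of them. SCNN1G, the gamma subunit of the epithelial sodium channel, rose by 1.43 ± 0.20 (adjusted p = 0.0118). The other large rises were FAIM2 at 1.67 ± 0.26, OR7C1 at 1.66 ± 0.19, CSRP2 at 1.54 ± 0.24, PNLIPRP3 at 1.47 ± 0.15 and the ectonucleotidase gene ENTPD3 at 1.41 ± 0.25, with adjusted p from 0.00172 to 0.0287. The rule that names these 10 genes requires their arrays to be separated in both site pairs.

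Among the falls, KRT15, a keratin of basal and hair follicle keratinocytes, decreased by 2.48 ± 0.32 (n = 6 against 6 arrays, adjusted p = 0.00778 in limma), with means of 6.64 ± 0.791 (SD, n = 6) in volar and 9.11 ± 0.538 (SD, n = 6) in non-volar arrays. PTGS2, the inducible cyclooxygenase, fell by 1.86 ± 0.18 (adjusted p = 0.00165). The MHC class II gene HLA-DQA2 fell by 1.66 ± 0.29 (adjusted p = 0.0282). NPY1R, a neuropeptide Y receptor, and F2R, a thrombin receptor, each fell by 1.49, with standard errors of 0.23 and 0.25. NPY1R is dim, with a mean of 3.73 in volar arrays, and was at -0.88 with a pseudocount of 16. TNFAIP3, an inhibitor of NF-kappaB signalling, fell by 1.34 ± 0.22, and POU2F3, a transcription factor of differentiating keratinocytes, fell by 1.18 ± 0.16 (adjusted p = 0.0106). MMD fell by 1.44 ± 0.26 and CCDC3 by 1.34 ± 0.21. SCEL, a precursor of the cornified envelope, fell by 1.24 ± 0.21. CLEC2A fell by 1.75 ± 0.29 and PMAIP1 by 1.34 ± 0.20, and ATF3 fell from a mean of 8.85 ± 0.852 (SD, n = 6) to 7.35 ± 0.953 (SD, n = 6). The genes of this paragraph printed without an adjusted p had values from 0.0166 to 0.0471.

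**Figure D1:**
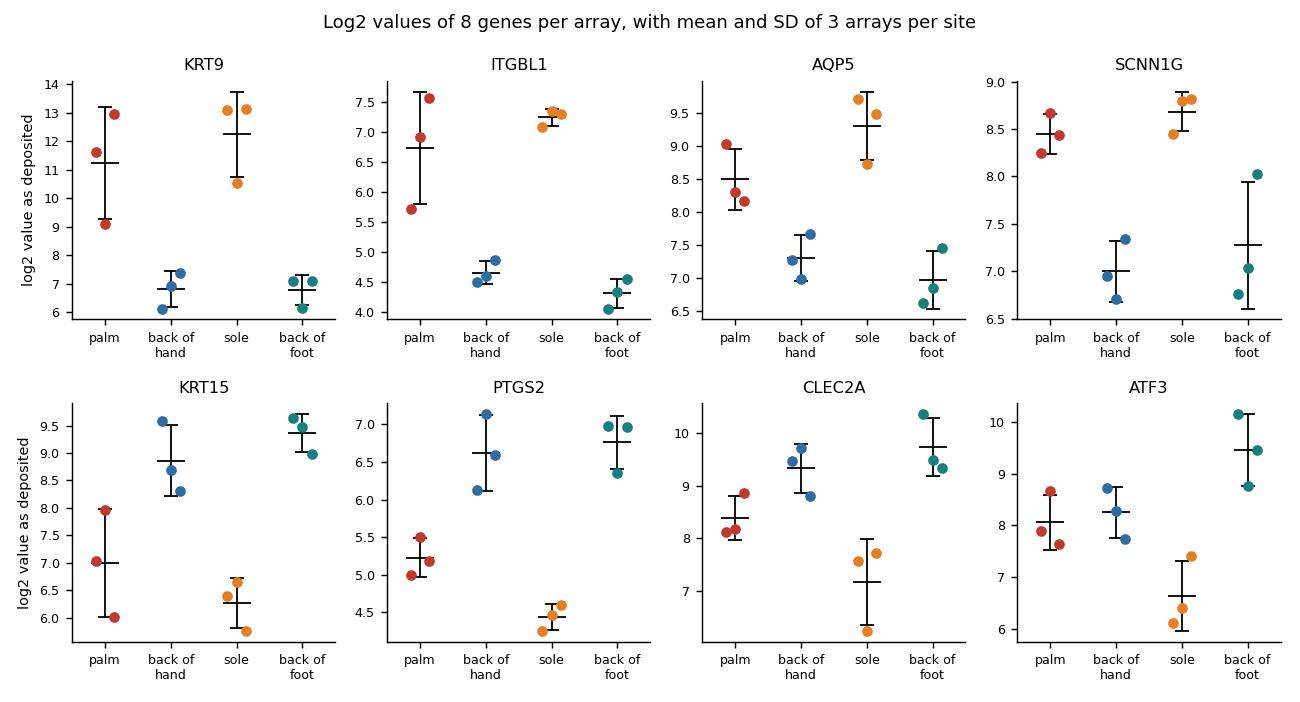
Each point is the deposited log2 value of one array (y axis) at one of 4 sites (x axis), with the mean as a dash and the SD of 3 arrays as bars, for 4 genes that rose and 4 that fell in volar epidermis. KRT9 averaged 11.2 in palms and 12.2 in soles against 6.82 and 6.78 on the backs of hand and foot. ATF3 averaged 8.06 in palms and 6.64 in soles, a change of -0.19 from the back of the hand and -2.82 from the back of the foot.

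In total 138 genes passed an adjusted p of 0.05, of which 63 rose and 75 fell, and 57 of them changed by at least 1 on the log2 scale. In 137 of the 138 genes the change had the same sign in hand and foot, and in 109 all 3 arrays of one site lay beyond all 3 of the other, in the same direction, in both site pairs. The 138 were selected on the mean of both pairs, which favours such counts. Of all 17393 genes tested 380 had this separation, where chance alone gives 0.5% of genes. The gene count moved when single arrays were left out. It fell to 32 without sole replicate 1, 36 without back of hand replicate 2, 37 without back of hand replicate 1, 45 without sole replicate 2, 52 without palm replicate 3, 70 without palm replicate 1, 83 without back of hand replicate 3, 84 without sole replicate 3, 94 without back of foot replicate 2 and 112 without palm replicate 2. It rose to 157 without back of foot replicate 1 and 182 without back of foot replicate 3. The count was 355 with the replicate number as a fixed block, 308 as a random block and 396 with array weights. Without both arrays of lowest correlation it was 118, of which 74 were among the 138.

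Genes whose variants cause palmoplantar keratoderma, a thickening of palm and sole skin, had a mean change of 0.48, with KRT9 at 4.94, and a median of 0.09 (camera adjusted p = 2.75e-04; adjusted p = 0.294 with an estimated correlation). Of 22 measured members 5 rose, 0 fell and 17 did not pass: KRT9, AQP5, the connexin genes GJB6 at 1.12 ± 0.21 and GJB2 at 1.12 ± 0.22, and the cathepsin gene CTSC at 0.80 ± 0.15, which was named after its value was seen. The same number, 5, rose when adjusted over the list alone. Among the 4 measured gap junction connexins GJB6 and GJB2 rose, also adjusted over the list alone, and GJA1 at 0.01 and GJB5 at -0.31 did not pass (camera adjusted p = 0.0682). Of 15 ion and water channel genes 3 rose, AQP5, SCNN1G and SCNN1B, the last by 0.84 ± 0.17. Adjusted over the list alone the same count rose and 1, CA2 at -0.43, fell (camera adjusted p = 0.124). SCNN1A, the alpha subunit of the same sodium channel, was at -0.05 and did not pass.

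Markers of Langerhans cells, the dendritic cells of the epidermis, were lower in volar epidermis by a mean of -0.61 and a median of -0.56 over 15 measured genes (camera adjusted p = 7.57e-09; adjusted p = 0.219 with an estimated correlation). Only FCGBP, at -1.16 ± 0.19, passed over all genes, and 9 fell adjusted over the list alone, among them CD207, the langerin gene, at -1.66 ± 0.35 (adjusted p over all genes 0.0558), HLA-DRA at -1.12 and CD1A at -0.98. Melanocyte markers were lower by a mean of -0.31 and a median of -0.40 over 15 genes (camera adjusted p = 3.51e-05; adjusted p = 0.219 with an estimated correlation). GPNMB fell by 0.60 ± 0.09 and OCA2 by 0.53 ± 0.10, while MITF at -0.38 and PMEL at -0.45 did not pass. Adjusted over the list alone 5 melanocyte markers fell and 1, ABCB5, rose. Melanogenesis paracrine factors averaged -0.24 over 8 genes, with 0 past the test over all genes and 1 lower adjusted over the list alone (camera adjusted p = 0.00487; adjusted p = 0.219 with an estimated correlation). In that list DKK3 was at -0.40 (adjusted p = 0.174), DKK1 at -0.05, EDN1 at -0.47 and KITLG at -0.42. DKK1, at 3.72 to 4.67 over the arrays, and KITLG, at 3.66 to 5.20, are dim. The list does not part factors that raise melanogenesis from factors that lower it, so its mean gives no direction of signalling. Its call was lost without back of foot replicate 1, with adjusted p from 0.00121 to 0.0693 over 21 alternatives.

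**Figure D2:**
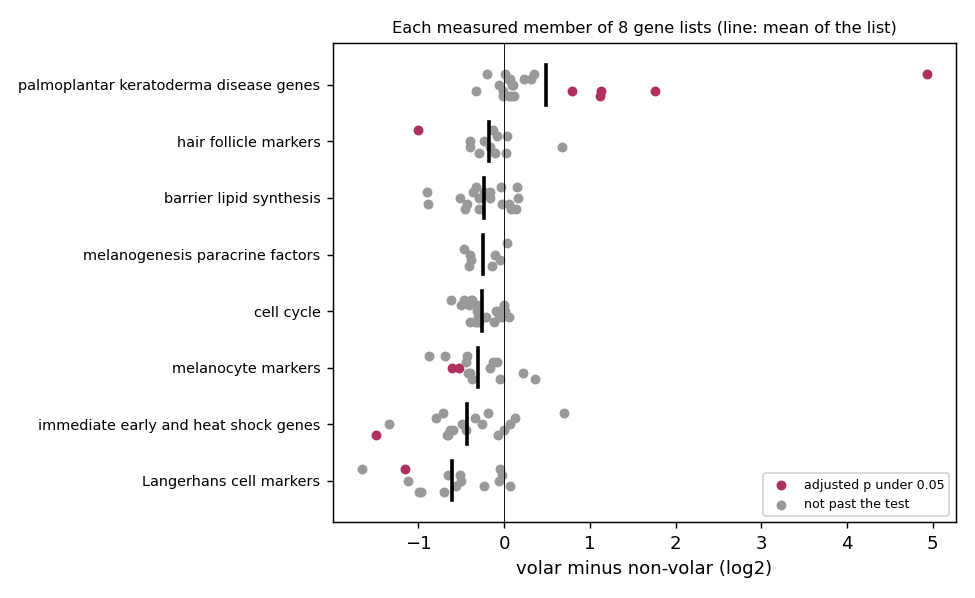
Each point is the change of one measured gene between volar and non-volar arrays (x axis, log2; n = 6 against 6) in the 8 gene lists with a camera adjusted p under 0.05 (y axis), red where the gene itself had an adjusted p under 0.05, and the black line is the list mean. The mean was 0.48 for keratoderma genes, where KRT9 lies at 4.94, and -0.61 for Langerhans cell markers, and none of the 8 calls remained with an estimated correlation.

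Immediate early and heat shock genes, which respond within minutes to stress and handling, averaged -0.43 with a median of -0.47 over 18 genes (camera adjusted p = 8.89e-05; adjusted p = 0.477 with an estimated correlation). ATF3 fell and FOS was at -0.59 ± 0.25 without passing. In palm against back of hand the list averaged -0.21 and did not pass (camera adjusted p = 0.737), with ATF3 at -0.19 there and at -2.82 in sole against back of foot. Between volar and non-volar arrays 6 members fell and 1, HSPH1, rose adjusted over the list alone. Cell cycle genes averaged -0.25 over 22 genes with 0 past the test in either adjustment, MKI67 at -0.41, NUSAP1 at -0.62 and TOP2A at -0.51 (camera adjusted p = 0.00121; adjusted p = 0.722 with an estimated correlation). The cell cycle call was lost without back of hand replicate 2 and without palm replicate 3, with adjusted p from 5.4e-08 to 0.169 over the 21 alternatives, and its mean was -0.12 without back of hand replicate 2, -0.16 without palm replicate 3 and -0.39 without palm replicate 2. Barrier lipid synthesis genes averaged -0.24 over 19 genes, none past the test, with UGCG, the glucosylceramide synthase gene, at -0.90 and LIPN at -0.89 (camera adjusted p = 0.00305; adjusted p = 0.477 with an estimated correlation). Adjusted over the list alone 1 of them fell. Hair follicle markers averaged -0.17 over 12 genes. GATA3 fell by 1.01 ± 0.14, and adjusted over the list alone 1 fell and 1 rose (camera adjusted p = 0.0444; adjusted p = 0.477 with an estimated correlation). The hair follicle call was lost without back of foot replicate 1, 2 or 3, palm replicate 1, sole replicate 2 or back of hand replicate 3, with adjusted p from 0.0092 to 0.146 over the alternatives.

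Differentiation genes as groups did not pass. Of 21 cornified envelope genes SCEL fell, and LORICRIN was at 0.08 ± 0.22. HRNR, the hornerin gene named after its value was seen, was at 3.71 ± 0.98 (adjusted p = 0.122), so that the list's mean was 0.04 while its median was -0.07 and the test pointed down (camera adjusted p = 0.324). Adjusted over the list alone 1 cornified envelope gene fell and 1 rose. The suprabasal keratins KRT1 at 0.23 ± 0.14, KRT10 at 0.04 ± 0.09, KRT2 at -0.25 ± 0.23 and KRT80 at -0.25 did not pass, with a list mean of -0.0022, a median of 0.04 and a test pointing up over 7 genes (camera adjusted p = 0.987). KRT10 was negative, at -0.03, with array weights. Of 8 basal layer genes KRT15 fell and KRT14 was at 0.10, with a list mean of -0.22, a median of 0.16 and a test pointing up (camera adjusted p = 0.953). Adjusted over the list alone 2 basal genes fell and 1 rose. SERPINB12 rose by 1.07 ± 0.18 among 15 desquamation genes, also adjusted over the list alone, with a list mean of 0.09, a median of -0.09 and a test pointing up (camera adjusted p = 0.953). The 18 desmosome and adherens junction genes included DSC2 at 0.87 and DSG3 at 0.76, with 0 past the test over all genes, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.387). The 7 LCE genes averaged -0.29, with LCE1F at -0.85 and LCE2A at -0.68 (camera adjusted p = 0.387). The 3 SPRR genes averaged 0.54, with SPRR2G at 1.80 ± 0.79, and adjusted over the list alone SPRR4 fell (camera adjusted p = 0.831). The 18 innate defence genes averaged 0.17, with IL36G at 1.19, RNASE7 at means of 5.69 in volar and 6.69 in non-volar arrays, and IL36G alone higher adjusted over the list alone (camera adjusted p = 0.0682). The 19 interferon response genes had a mean of 0.02, a median of -0.02 and a test pointing down, with OAS2 at 0.89 and OAS1 at 0.75 both higher adjusted over the list alone (camera adjusted p = 0.578).

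Of signalling genes, WNT5A, a ligand of WNT signalling outside the beta-catenin route, rose by 1.33 ± 0.24 and WNT3 fell by 1.02 ± 0.20 among 19 WNT ligands, of which 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.315). The 16 WNT antagonists had 0 past the test, SFRP1 at 0.41, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.513). BAMBI rose by 0.96 ± 0.14 among 14 WNT target genes in both adjustments (camera adjusted p = 0.167). ID4, an inhibitor of helix-loop-helix transcription factors, fell by 1.07 ± 0.17 among 19 BMP pathway genes, of which 2 fell adjusted over the list alone, with a list mean of -0.14, a median of 0.02 and a test pointing down (camera adjusted p = 0.324). HBEGF fell by 1.15 ± 0.20 among 11 EGF receptor ligands and receptors in both adjustments (camera adjusted p = 0.167). The 19 retinoid genes included RDH10 at 0.43 and CYP26B1 at 0.41, with 1 higher adjusted over the list alone (camera adjusted p = 0.379).

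Positional genes did not pass in this comparison. EN1, a ventral limb determinant, was at 0.54 ± 0.11 with an adjusted p of 0.0542 over all genes, WNT7A, a dorsal signal, at -0.16 and LMX1B, its dorsal target, at 0.08. LMX1B turned to -0.07 with the mean of all entries of a gene. Among 14 dorsoventral patterning genes 1, EN1, was higher and BMP2 at -0.69 was lower adjusted over the list alone (camera adjusted p = 0.912). Of 8 limb identity genes 3 were higher adjusted over the list alone, MEIS1 at 0.88, EMX2 at 0.43 and MEIS2 at 0.35 (camera adjusted p = 0.281). TBX5 was at 0.04, TBX4 at -0.17 and PITX1 at 0.03. The 8 HOXB genes included HOXB2 at -0.24 and HOXB13 at 0.12, with a mean of -0.02, a median of 0.0034 and a test pointing down (camera adjusted p = 0.953). HOXC9 at 0.40 was higher adjusted over the list alone among 6 HOXC genes, with HOXC11 at 0.25 and HOXC10 at -0.11 (camera adjusted p = 0.137). The 7 HOXD genes had 0 past the test in either adjustment, with HOXD10 at -0.37, HOXD11 at -0.20 and HOXD13 at -0.02 (camera adjusted p = 0.491). HOXD13 was positive, at 0.0037, with array weights.

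Lists of other cell types did not pass. The mean level was 4.40 for T cell, 4.87 for endothelial and 5.14 for Merkel cell markers, below the array medians of 5.16 to 5.28. Since the background is unknown, a change in such dim markers may go unseen. Of 20 eccrine gland markers AQP5 rose in both adjustments and DCD, the sweat gland peptide gene, was at 0.04 ± 0.23, or -0.21 without sole replicate 1 (camera adjusted p = 0.513). The 17 fibroblast markers averaged 0.06, VIM fell by 0.87 ± 0.14 in both adjustments and COL1A1 was at 0.21 (camera adjusted p = 0.281). The 13 T cell markers had a mean of -0.02, a median of 0.05 and a test pointing up, with CD69 at -0.41 and CD4 at -0.31 (camera adjusted p = 0.953). The 13 Merkel cell markers averaged 0.03, with SOX2 at -0.65 and ATOH1 at 0.27 (camera adjusted p = 0.324). Sebaceous markers averaged -0.05 over 20 genes, with FABP7 at -0.82, PLIN2 at -0.55 and 1 lower adjusted over the list alone (camera adjusted p = 0.391). The 13 endothelial markers averaged 0.03 with a median of -0.0018 and a test pointing up, VWF at 0.22 and KDR at 0.16 (camera adjusted p = 0.793). The 8 smooth muscle markers had a mean of -0.0034, a median of 0.02 and a test pointing up, with ACTG2 at -0.23 and LMOD1 at 0.10 (camera adjusted p = 0.953). The 5 blood markers averaged -0.04, with AHSP at -0.11 and CA1 at -0.06 (camera adjusted p = 0.491). In the lists of this paragraph no other gene passed over all genes.

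The next comparison asked what differs between palm and back of hand. PPM1K rose by 1.48 ± 0.12 (n = 3 against 3 arrays, adjusted p = 9.49e-04 in limma), from a mean of 4.31 ± 0.131 (SD, n = 3) to 5.79 ± 0.110 (SD, n = 3), and was the only gene to pass. It is among the dimmest 33% of genes. With the replicate number as a block, which the data of this pair met the condition for, 2 genes passed: PPM1K with an adjusted p of 0.00321, and SEMA6D, a semaphorin gene named after its value was seen, at 1.06 with an adjusted p of 0.0134. KRT9 was at 4.41 ± 0.89, ITGBL1 at 2.09 ± 0.35, AQP5 at 1.19 ± 0.31, SCNN1G at 1.45, KRT15 at -1.86 ± 0.45 and PTGS2 at -1.40, none of them past the test over all genes. In limma 1034 genes had an unadjusted p under 0.05, where chance alone gives 870. PPM1K did not pass when its site pair was fitted alone, which left 0 genes, and the count was 3 without back of foot replicate 1 and 3 without palm replicate 1.

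Gene groups differed in palm as follows. Cornified envelope genes averaged -0.31 over 21 genes (camera adjusted p = 9.98e-04; adjusted p = 0.398 with an estimated correlation), with 0 members past the test in either adjustment. LCE genes averaged -0.70 over 7 genes (0.0125; adjusted p = 0.525 with an estimated correlation) and barrier lipid genes -0.34 over 19 (0.00154; adjusted p = 0.372 with an estimated correlation), again with 0 members past. Langerhans cell markers averaged -0.57 (camera adjusted p = 3.9e-05; adjusted p = 0.353 with an estimated correlation) and melanocyte markers -0.34 (9.98e-04; adjusted p = 0.332 with an estimated correlation), each with 0 members past over all genes and 1 lower adjusted over the list alone. Melanogenesis factors averaged -0.31 (camera adjusted p = 0.00531; adjusted p = 0.332 with an estimated correlation). Hair follicle markers averaged -0.38 (camera adjusted p = 5.18e-04; adjusted p = 0.332 with an estimated correlation) with 2 lower adjusted over the list alone, and sebaceous markers -0.18 (0.0492; adjusted p = 0.332 with an estimated correlation). HOXD genes averaged -0.33, with HOXD10 at -0.92 and HOXD11 at -0.64 lower adjusted over the list alone (camera adjusted p = 0.00694; adjusted p = 0.363 with an estimated correlation). Cell cycle genes averaged -0.35 (camera adjusted p = 0.00761; adjusted p = 0.837 with an estimated correlation). Keratoderma genes averaged 0.35, with 3 higher adjusted over the list alone (camera adjusted p = 0.00531; adjusted p = 0.363 with an estimated correlation). WNT ligands averaged -0.18, with 2 lower adjusted over the list alone (camera adjusted p = 0.0287; adjusted p = 0.647 with an estimated correlation), and with the replicate block their adjusted p was 0.0564. Connexins passed with the block only, at 0.0172 against 0.0806 without it. Without palm replicate 1 the LCE call was lost (mean -0.34, adjusted p = 0.131) and the melanocyte mean was -0.21. Without palm replicate 2 the WNT ligand (0.0772) and HOXD (0.0600) calls were lost, and the LCE and cell cycle means were -1.06 and -0.62. Without palm replicate 3 the LCE (0.0891), keratoderma (0.0819), cell cycle (mean -0.15, 0.881) and WNT ligand (0.0855) calls were lost. Without back of hand replicate 1 the barrier lipid (0.10) and WNT ligand (0.13) calls were lost and the Langerhans mean was -0.37. Without back of hand replicate 2 the cell cycle (mean -0.088, 0.980), WNT ligand (0.156) and melanogenesis (0.0516) calls were lost. The sebaceous call was kept only without palm replicate 1, back of hand replicate 2 or sole replicate 3, with an adjusted p of up to 0.195 without 1 of the other arrays.

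Between sole and back of foot, KRT9 rose by 5.46 ± 0.89 (n = 3 against 3 arrays, adjusted p = 0.0326 in limma), ITGBL1 by 2.95 ± 0.35 (adjusted p = 0.00542) and AQP5 by 2.33 ± 0.31 (adjusted p = 0.0120). FAIM2 rose by 2.11 ± 0.36 and OR7C1 by 2.05 ± 0.27. KRT15 fell by 3.09 ± 0.45 (adjusted p = 0.0203) and PTGS2 by 2.33 ± 0.25 (adjusted p = 0.00374). The stress-response genes ATF3, which fell by 2.82 ± 0.42 (adjusted p = 0.0243), and PMAIP1, a BCL2 family gene that fell by 2.22, were among the largest falls, with CLEC2A at -2.55. Named after their values were seen, JUN fell by 1.38 ± 0.23, TRIB1 by 1.65 ± 0.25 and PLK2 by 1.87 ± 0.32, and the heat shock gene HSPH1 rose by 1.39 ± 0.23.

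Immediate early and heat shock genes averaged -0.66 between sole and back of foot over 18 genes, of which ATF3 and JUN fell and HSPH1 rose over all genes, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.27e-06; adjusted p = 0.328 with an estimated correlation). Langerhans cell markers averaged -0.64, with 0 past over all genes and 5 lower adjusted over the list alone (camera adjusted p = 1.27e-06; adjusted p = 0.328 with an estimated correlation). Melanocyte markers averaged -0.27 with 4 lower adjusted over the list alone (camera adjusted p = 0.00337; adjusted p = 0.328 with an estimated correlation). Keratoderma genes averaged 0.62, with KRT9 and AQP5 higher over all genes and 6 higher adjusted over the list alone (camera adjusted p = 0.00360; adjusted p = 0.328 with an estimated correlation). Retinoid genes averaged 0.23, with 2 higher adjusted over the list alone (camera adjusted p = 0.0243; adjusted p = 0.520 with an estimated correlation). The retinoid call was lost without back of foot replicate 1 (mean 0.11, adjusted p = 0.163) and without back of foot replicate 2 (0.147).

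In the foot 47 genes passed, 23 higher and 24 lower in the sole, and 41 of them were among the 138. Of the 47, 43 had the same sign in the hand and 26 also had an unadjusted p under 0.05 there. The count was 16 without sole replicate 1, 20 without sole replicate 2, 25 without back of foot replicate 1, 26 without back of hand replicate 2, 29 without palm replicate 3 and 30 without back of hand replicate 3. It rose to 61 without palm replicate 1 and 66 without back of foot replicate 3. The same count was 172 with the replicate number as a fixed block, 117 as a random block and 88 with array weights. It was 5 when the site pair was fitted alone. Across genes, which are not independent replicates, the changes in hand and foot correlated with a Pearson r of 0.253 and a Spearman rho of 0.084, and 45.2% of all genes had the same sign in both pairs. Of 100 splits of the arrays within hand and foot, 17, the real one included, gave an r as large, up to 0.459.

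**Figure D3:**
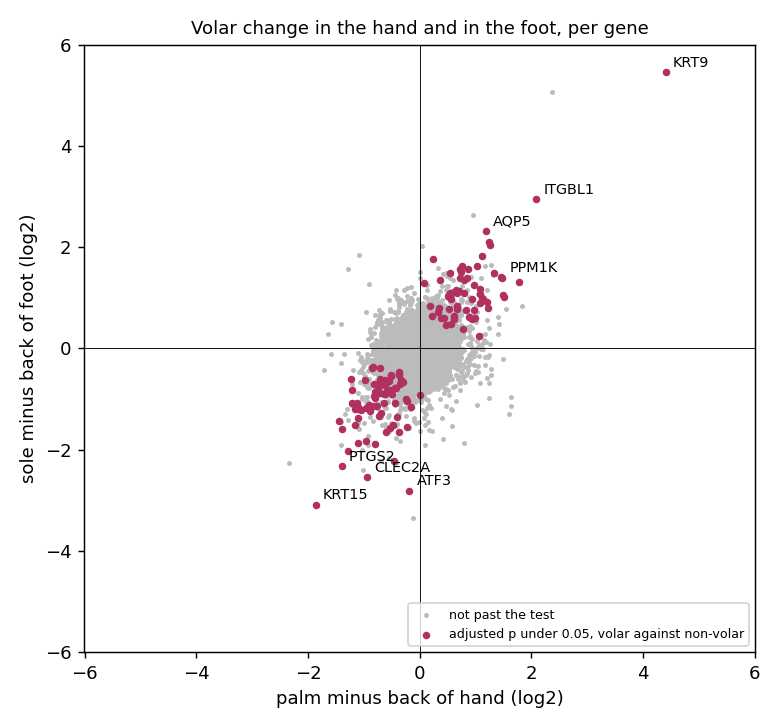
Each point is one of 17393 genes, with its palm minus back of hand change (x axis, log2; n = 3 against 3) and its sole minus back of foot change (y axis, log2; n = 3 against 3), red where volar against non-volar had an adjusted p under 0.05. KRT9 lies at 4.41 and 5.46, KRT15 at -1.86 and -3.09, and ATF3, red as well, at -0.19 and -2.82.

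Whether the volar change differed between hand and foot was tested directly. ATF3 had a hand minus foot difference of 2.63 ± 0.60 (n = 3 arrays per site, adjusted p = 0.729 in limma). PLK2 at 2.67, JUN at 1.78, the Merkel cell gene ATOH1 at -1.27 and ABCG4 at -1.22, named after their values were seen, each had an adjusted p of 0.662. In limma 0 genes passed, 885 had an unadjusted p under 0.05 (870 by chance alone), and 0 passed with the replicate block, with a random block and with array weights. The median of all genes was -0.12 in this contrast and -0.039 without back of foot replicate 1. Lists with camera calls were immediate early and heat shock genes at a mean of 0.45 (adjusted p = 8.04e-04) and, lower, cornified envelope genes at -0.69, desquamation genes at -0.71, LCE genes at -0.82, HOXD genes at -0.51, hair follicle markers at -0.42, retinoid genes at -0.35, dorsoventral genes at -0.33 and endothelial markers at -0.24. All 9 calls were lost with an estimated correlation, where the smallest adjusted p was 0.517, and fry called 2 lists. The HOXD and retinoid calls were kept in all 12 fits that left out 1 array, with a retinoid mean of -0.22 without back of foot replicate 1. Without that array the dorsoventral call was lost (mean -0.20, adjusted p = 0.0562). Without back of foot replicate 3 the cornified envelope (0.0536), LCE (mean -0.50, 0.298), desquamation (0.101), immediate early and heat shock (mean 0.23, 0.101), hair follicle (0.0663) and endothelial (0.101) calls were lost. Without palm replicate 1 the LCE (mean -0.46, 0.146), desquamation, hair follicle and endothelial calls (0.0554 each) were lost. Without back of foot replicate 2 the dorsoventral, hair follicle and endothelial calls (0.0737 each) were lost. The LCE call was also lost without palm replicate 3 (0.102) and back of hand replicate 2 (0.0588), the dorsoventral call without palm replicate 2 (0.0991) and sole replicate 3 (0.0823), and the endothelial call without sole replicate 1 (0.162), back of hand replicate 3 (0.0796) and palm replicate 3 (0.0899).

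**Figure D4:**
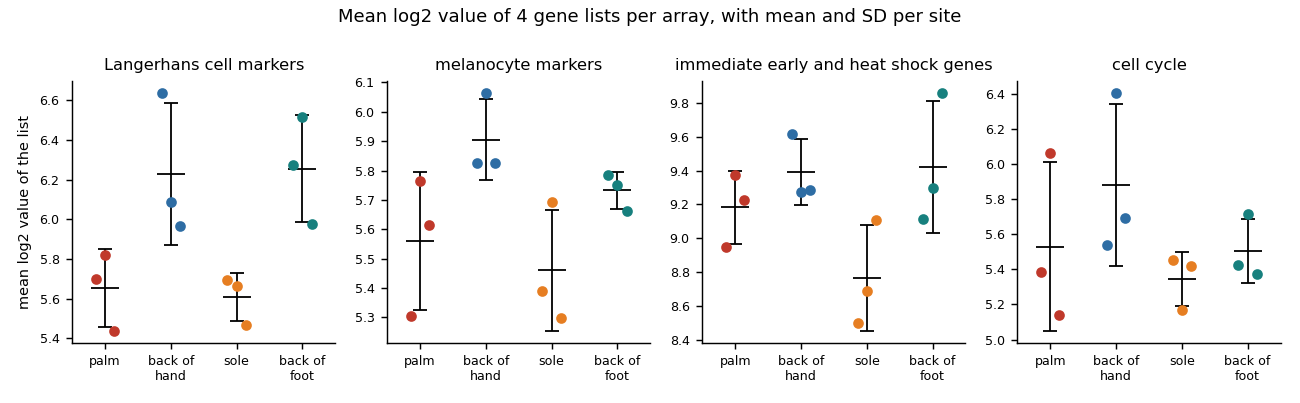
Each point is the mean log2 value of one gene list in one array (y axis) at one of 4 sites (x axis), with the site mean as a dash and the SD of 3 arrays as bars, for 4 lists. The immediate early and heat shock mean was 8.50, 8.69 and 9.11 in the 3 soles and 9.11, 9.30 and 9.86 in the 3 backs of foot, and the cell cycle mean was highest, at 6.40, in back of hand replicate 2.

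The comparison of lower with upper extremity asked for differences of position along the body. HOXD genes, which pattern the limb, averaged -0.33 over 7 genes, all below 0, and 6 of them fell adjusted over the list alone (camera adjusted p = 3.8e-05; adjusted p = 0.537 with an estimated correlation). Their mean was -0.58 between the backs of foot and hand and -0.07 between sole and palm, where the list did not pass (camera adjusted p = 0.561). HOXA2 was at 0.82 ± 0.12 (n = 6 against 6 arrays, adjusted p = 0.174 in limma), and KIAA0040, named after its value was seen as was this result of HOXA2, at -0.62 ± 0.09 (adjusted p = 0.174). The hindlimb factors PITX1 at -0.52 ± 0.10 and TBX4 at -0.04, and the forelimb factor TBX5 at -0.11, did not pass. Dorsoventral genes averaged -0.19 (camera adjusted p = 0.00335), cell cycle genes -0.28 (0.00335), cornified envelope genes -0.17 (0.0240), barrier lipid genes -0.22 (0.0240) and WNT ligands -0.14 (0.0241), with 0 members past the test in either adjustment and an adjusted p of 0.783 each with an estimated correlation. In limma 0 genes passed and 1223 had an unadjusted p under 0.05 (870 by chance alone), with 0 also under both block models and array weights, and fry called 0 lists. The HOXD and dorsoventral calls were kept in all 12 fits that left out 1 array, with a dorsoventral mean of -0.12 without back of foot replicate 1. The cornified envelope call was lost without back of foot replicate 1 (mean -0.11, 0.0594), back of foot replicate 3 (0.0820), back of hand replicate 1 (0.112), palm replicate 3 (0.0943) and sole replicate 2 (mean -0.081, 0.195). The barrier lipid call was lost without back of foot replicate 3 (0.175), back of hand replicate 1 (0.124), back of hand replicate 2 (0.0787), palm replicate 2 (0.0539) and sole replicate 2 (0.117). The cell cycle call was lost without back of hand replicate 2 (mean -0.15, 0.281), palm replicate 2 (mean -0.15, 0.196) and back of foot replicate 3 (0.119). The WNT ligand call was lost without back of foot replicate 1 (0.0589), back of foot replicate 3 (0.0650), back of hand replicate 1 (0.104), back of hand replicate 2 (0.136), sole replicate 2 (0.0765) and sole replicate 3 (0.0565).

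Between sole and palm, immediate early and heat shock genes averaged -0.42 over 18 genes (camera adjusted p = 2.3e-05; adjusted p = 0.801 with an estimated correlation), with 3 lower and 1 higher adjusted over the list alone. Cell cycle genes averaged -0.18 over 22 genes with 0 past the test (camera adjusted p = 0.0414; adjusted p = 0.892 with an estimated correlation). That call was lost without palm replicate 2 (mean 0.084, adjusted p = 0.805), sole replicate 2 (mean -0.094, 0.267), back of foot replicate 1 (0.108) and back of foot replicate 3 (0.0582), and the mean was -0.38 without palm replicate 3. HOXD genes averaged -0.07 and dorsoventral genes -0.02, with HOXD10 at 0.04, and neither list passed (camera adjusted p = 0.561 and 0.718). HOXA2 was at 0.97 ± 0.17, TRIB1 at -1.45 ± 0.25, PLK2 at -1.79 ± 0.32, the immunoproteasome gene PSMB8 at -0.71 ± 0.13 and the linker histone gene H1-10 at -1.02 ± 0.17, all named after their values were seen (n = 3 against 3 arrays, adjusted p = 0.419 each in limma). In limma 0 genes passed, 594 had an unadjusted p under 0.05 (870 by chance alone) and 0 passed with the replicate block, whose condition this pair met, while 5 passed with array weights.

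Between the backs of foot and hand the median of all genes was -0.11, and it was -0.019 without back of foot replicate 1. HOXD genes averaged -0.58 over 7 genes, all below 0, with HOXD10 at -1.07 ± 0.23 and HOXD11 at -0.89 ± 0.18 among the 5 that fell adjusted over the list alone (camera adjusted p = 3.2e-05; adjusted p = 0.519 with an estimated correlation; fry adjusted p = 0.0103). Cornified envelope genes averaged -0.52 (camera adjusted p = 7.28e-04), LCE genes -0.71 (0.0177) and desquamation genes -0.55 (0.0155). Hair follicle markers averaged -0.40 (camera adjusted p = 0.00518), retinoid genes -0.28 (0.00457), WNT ligands -0.26 (0.0104), dorsoventral genes -0.35 (9.51e-04) and endothelial markers -0.18 (0.0460). With an estimated correlation their adjusted p was 0.524, 0.542, 0.524, 0.524, 0.524, 0.524, 0.524 and 0.697 in the same order. With the replicate block, whose condition this pair met, endothelial markers had an adjusted p of 0.0730 and cell cycle genes 0.0241 against 0.0590 without it. Without back of foot replicate 1 the means were -0.27 for hair follicle markers, -0.15 for retinoid genes, -0.16 for WNT ligands, -0.22 for dorsoventral genes and -0.11 for endothelial markers, whose call was lost (0.0551). Without back of foot replicate 3 the LCE (mean -0.39, 0.407), desquamation (0.134), WNT ligand (0.0614) and endothelial (0.125) calls were lost. Without back of foot replicate 2 the retinoid (0.0588) and endothelial (0.0864) calls were lost, and without back of hand replicate 2 the WNT ligand call (0.0764). The endothelial call was also lost without palm replicate 1 (0.0553), palm replicate 3 (0.0514), back of hand replicate 3 (0.144) and sole replicate 3 (0.0549). SPRR4, a cornified envelope precursor, was at -1.06 ± 0.15 (n = 3 against 3 arrays, adjusted p = 0.223 in limma), PITX1 at -0.86 ± 0.15 (adjusted p = 0.476) and ATOH1, named after its value was seen, at -1.03 ± 0.16 (adjusted p = 0.418). In limma 0 genes passed and 1812 had an unadjusted p under 0.05 (870 by chance alone), with 0 also under both block models and array weights.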

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

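The tests of Langerhans cell and melanocyte markers and of AQP5, SCNN1B and SCNN1G were chosen only after their results were seen. Within the 6 volar and the 6 non-volar arrays, 68 measures gave 136 groups, and 19 had an array standing apart from the rest by Dixon's ratio of its gap to the nearest array over the range, where chance at 1 in 20 gives 6.8. Back of foot replicate 1 stood apart among the non-volar arrays in its median (ratio 0.626), its mean Spearman correlation with the other arrays (0.856), and the values of SERPINB12 (0.801), KRT1 (0.646), TBX4 (0.764), HOXC10 (0.880) and DCD (0.636). Palm replicate 1 stood apart among volar arrays in ITGBL1 (0.655), KRT14 (0.643) and LMX1B (0.631). Palm replicate 2 did so in NPY1R (0.629), EN1 (0.667) and the mean of the cell cycle list (0.661), and back of hand replicate 2 did so among non-volar arrays in the cell cycle mean (0.670). Palm replicate 3 stood apart in GJB2 (0.793), sole replicate 1 in POU2F3 (0.870) and DCD (0.832), sole replicate 2 in HOXD13 (0.804), and back of hand replicate 3 in PMAIP1 (0.630).

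The volar change differed between hand and foot for 9 gene lists by camera's test of the difference, with all 9 calls lost with an estimated correlation (smallest adjusted p = 0.517). The adjusted p was 0.00323 for the cornified envelope, retinoid and HOXD lists, 0.0329 for the LCE genes and the endothelial markers, 0.0103 for desquamation genes, 8.04e-04 for immediate early and heat shock genes, 0.0244 for dorsoventral patterning and 0.0191 for hair follicle markers. The HOXD and retinoid calls were kept in all 12 fits that left out 1 array, and each of the other 7 was lost in at least 1 of them.

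Langerhans cell and melanocyte markers were lower in volar epidermis, by means of -0.61 and -0.31. The tables argue against a single array, since both lists kept an adjusted p under 0.05 in all 12 fits that left out 1 array, while neither passed with an estimated correlation (adjusted p = 0.219 each). Relabelling arrays within extremities gave a two-sided exact permutation p of 0.005 for the Langerhans mean and 0.01 for the melanocyte mean. With 400 relabellings 0.005 is the smallest possible value. Both lists were picked after their results were seen, and these p-values are not adjusted. Dilution by more keratinocyte RNA could lower both alike: the difference of the list means, -0.30, had an exact permutation p of 0.1 (two-sided, within extremities), and the Merkel cell mean moved by 0.03 with an exact p of 0.525. Merkel cell markers are dim, at a mean level of 5.14, so a fall in them may go unseen. The p of 0.1 does not show that both lists fell alike, so dilution and a lower number of Langerhans cells and melanocytes in volar skin cannot be told apart with 6 arrays each. A lower level of the transcripts per cell was not tested.

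The list of immediate early and heat shock genes was lower in soles than on backs of feet, with a mean of -0.66 over 18 genes, of which ATF3 and JUN fell and HSPH1 rose over all genes in limma. The 14 immediate early members, with a mean of -0.97 and all below 0, and the 4 heat shock members, with a mean of 0.42 and 1 below 0, were not tested on their own. The tables argue against a single array, since the list kept an adjusted p under 0.05 in all 12 fits that left out 1 array, from 1.36e-09 to 0.00663, while it did not pass with an estimated correlation (adjusted p = 0.328). Handling before RNA was stabilised was not decided: the SD of the list mean between arrays of a site, 0.289, was above that of 99.9% of random lists, but genes of a random list do not vary together, and the SPRR (0.564), LCE (0.480) and cell cycle (0.354) lists varied more. Handling and a difference between the sites themselves cannot be told apart, since handling times are not given in the sources used here.

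AQP5, SCNN1B and SCNN1G were higher in volar epidermis. The other 19 measured eccrine markers, of which KRT8, KRT18 and KRT77 stand in other lists too, had a median change of 0.042 (SD 0.246). DCD changed by 0.04 with an upper bound of 0.53 against a lower bound of 1.27 for AQP5. DCD is dim, at a mean level of 5.43 near the array medians of 5.16 to 5.28, so a rise in it may go unseen. RNA of the eccrine secretory coil as the source of AQP5 is therefore argued against only as far as these markers lie above the unknown background. A larger granular layer as the source of SCNN1G is argued against, since 21 cornified envelope and granular layer genes had a median of -0.068 (SD 0.90) against a lower bound of 0.99 for SCNN1G. For SCNN1B the granular layer stays open. A higher level of these transcripts in volar keratinocytes and RNA of sweat ducts both stay open as hypotheses, and neither was tested separately.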

How the results depend on the processing

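Leaving out the pair of arrays with the lowest mean correlation and testing all table entries together were chosen only after the results were seen. The number of genes changed volar vs non-volar, 138, was 83 with a pseudocount of 16, 396 with array weights, 355 with the replicate block, 308 with a random block, 57 with a change of at least 1, 318 at an adjusted p of 0.1 and 33 when all table entries were tested, and 32 to 182 with 1 array left out. The palm count of 1 was 0 without the dimmest genes, 22 with array weights, 2 with the replicate block, 0 with only the sites compared and 2 without both arrays, and 1 to 3 with 1 array left out. The sole count of 47 was 21, 88, 172 and 117 with the pseudocount, array weights, the replicate block and the random block, 5 with only the sites compared and 129 at an adjusted p of 0.1, and 16 to 66 with 1 array left out. The sole against palm count of 0 was 5 with array weights and 1 without both arrays. The 8 volar list calls became 0 with an estimated correlation, 5 with fry and 5 without both arrays, and 6 to 9 with 1 array left out. The looser threshold and the minimum change account for their own changes by construction, and leaving out the dimmest genes removed PPM1K, the only gene called in palm, from the test; for the other settings the cause was not tested. All 138 genes were among those called with either block and 134 among those called with array weights, and all 83 called with the pseudocount were among the 138. The counts for the difference between hand and foot, the extremities and the backs of foot and hand were 0 in limma under every alternative run. The correlation of palm and sole changes, 0.253, ran from 0.110 to 0.486 with 1 array left out.

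Among named genes KRT9, ITGBL1, AQP5, OR7C1, PNLIPRP3, SCNN1G, KRT15, PTGS2, POU2F3, BAMBI and GATA3 passed in all 21 alternatives and PPM1K in the 20 that include it. GJB2, WNT3 and ATF3 passed in 8, SCNN1B in 9, and MMD and WNT5A in 10 of them, with the same direction. Of 37 called named genes 14 passed without back of hand replicate 1, 14 without sole replicate 1, 15 without back of hand replicate 2, 21 without palm replicate 3 and 22 without sole replicate 2. Some genes that did not pass changed sign. With array weights KRT10 was -0.030 and HOXD13 0.0037, and with the mean of all entries LMX1B was -0.069. Without both arrays the log2 fold change of KRT10 was -0.00725 and DCD -0.042. With 1 array left out the log2 fold change of LMX1B ran from -0.00804 to 0.20. The change in these fits ran from -0.022 to 0.19 for KRT14, -0.13 to 0.26 for LORICRIN, -0.13 to 0.051 for DKK1, -0.011 to 0.11 for TBX5, -0.038 to 0.070 for PITX1, -0.30 to 0.0035 for HOXC10, -0.10 to 0.10 for HOXD13 and -0.21 to 0.18 for DCD; the cause was not tested. The Langerhans, melanocyte, keratoderma, barrier lipid and immediate early calls were kept in all 21 alternatives of camera at the preset correlation, the hair follicle call in 12, the cell cycle call in 18 and the melanogenesis call in 19. The replicate block changed list calls also outside the pairs that met the pairing condition: connexins passed in volar skin (0.0270 against 0.0682), limb identity genes (0.0370 against 0.0673) and fibroblast markers (0.0370 against 0.0696) in soles, and for the difference between hand and foot fibroblast markers passed (0.0365 against 0.0709) and endothelial markers did not (0.0688 against 0.0329). It changed no list call beyond these and those given with the palm and the backs of foot and hand. Signal over background is unknown for these arrays, so a dim gene that did not pass may lie at background.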

Other observations

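The tests on splits were chosen beforehand; the genes in this part were chosen only after their values were seen. They are single genes, not a test of a group: the fixed list of ion and water channels did not pass (camera adjusted p = 0.124). TFCP2L1, a transcription factor of salt-transporting ducts, rose in volar epidermis by 1.28 ± 0.17 (SE, n = 6 against 6 arrays, adjusted p = 0.00903 in limma). SGK1, a kinase that raises sodium channel activity, rose by 0.58 ± 0.10 (adjusted p = 0.0304). The cation channel gene NALCN rose by 1.08 ± 0.16 and the potassium channel gene KCNJ15 by 0.75 ± 0.14. The iron oxidase gene HEPH rose by 1.02 ± 0.11 and the metallothionein gene MT1X by 1.05 ± 0.18. The Notch ligand gene DNER rose by 0.90 ± 0.09 and PRICKLE1, of planar cell polarity, by 1.12 ± 0.17. DDIT4, an inhibitor of mTOR signalling, rose by 0.95 ± 0.16, and the clock gene CRY1 fell by 0.77 ± 0.11. The genes without an adjusted p here had values from 0.00165 to 0.0325.

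Among single genes outside the lists, LCP1, an actin bundling protein of blood cells, fell in volar epidermis by 1.07 ± 0.15 (SE, n = 6 against 6 arrays, adjusted p = 0.0118 in limma), MPEG1, a macrophage pore protein, by 0.81 ± 0.14, LAPTM5 by 0.67 ± 0.12, PRKCB by 0.70 ± 0.12, ALOX5 by 0.66 ± 0.13 and NCKAP1L by 0.41 ± 0.08. Those without an adjusted p here had values from 0.0285 to 0.0467. Whether these falls are separate from that of the Langerhans cell markers was not tested. The mean of the T cell list was at -0.02, with an exact permutation p of 0.765, and no list of leukocytes other than Langerhans and T cells was tested. T cell markers are dim, at a mean level of 4.40, so a change in them may go unseen. In soles the MHC class I chain gene B2M fell by 1.63 ± 0.28 against the back of the foot (n = 3 against 3 arrays, adjusted p = 0.0420 in limma) and the immunoproteasome gene PSMB8 by 0.93 ± 0.13. In the hand B2M was at 0.0074 and PSMB8 at 0.0079. The volar change of B2M and PSMB8 did not pass the test of a difference between hand and foot (adjusted p = 0.729 each in limma).

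The cell cycle mean was 6.40 in back of hand replicate 2, 6.06 in palm replicate 2 and 5.71 in back of foot replicate 2, against 5.17 in sole replicate 2.

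Of 100 splits of the arrays within hand and foot, only the real one, with 138 genes, reached the volar gene count, and the highest other gave 8. Chance cannot be excluded for the number of volar lists called, where 7 splits reached the real 8 and the highest other was 12. Nor can it be for the correlation of palm and sole changes, where 17 reached the real 0.253 and the highest other was 0.459. The count of lists does not test any single list. The real split keeps the replicate numbers balanced, and these splits were not separated by whether they do. If the numbers carry an effect, unbalanced splits are noisier than the real one, so these splits cannot exclude chance for the gene count either. Another 100 splits exchanged hand and foot arrays within volar and within non-volar sites. The real gene counts, for the difference between hand and foot and for the extremities, were 0, which all 100 splits reach by definition, so they decide nothing about chance (highest other 1 and 2). Chance cannot be excluded for the number of lists, where 6 splits reached the real 9 of the difference (highest other 13) and 14 the real 6 of the extremities (highest other 13). These splits, too, were not separated by whether they keep the replicate numbers balanced, which limits this comparison. For a pair of sites the 10 splits are too few for a share under 0.05. The real value and the highest other were 1 and 0 genes and 12 and 10 lists for palm against back of hand, 47 and 1 genes and 5 and 6 lists for sole against back of foot, 0 and 1 genes and 2 and 10 lists for sole against palm, and 0 and 1 genes and 9 and 7 lists for the backs of foot and hand. Among the 4 splits that part all 3 replicate numbers, as the real split does, the highest other was 0 genes and 6 lists for palm against back of hand, 0 genes and 6 lists for sole against palm, and 0 genes and 7 lists for the backs of foot and hand, and the 6 splits that part 1 number gave up to 0, 1 and 1 genes and up to 10, 10 and 5 lists in the same order.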
